A study of Macaca mulatta with 6 samples.

How the data were processed

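Total RNA from jejunal tissue of 3 SIV-infected and 3 uninfected rhesus macaques was extracted with Qiagen RNeasy kits, and biotin-labelled cRNA was made by Affymetrix protocols, per the labels' protocols. The deposited values are 1 number per probe set and array for 52766 probe sets, on a scale that was read as log2 from their range of 1.45 to 14.21. The log base, the background correction, the summary of probes into probe sets and the normalization between arrays are not given in the sources used here. Partek 6.6 is named in the submitters' processing notes, with no role stated. All differences in log2 units and all folds therefore rest on reading the scale as log2. The table held no control probe sets with the AFFX prefix and 0 columns of other samples. Scanner files, detection calls, scan dates and the sex of the animals were not used here, so batches could not be tested, and no probe set could be called above or below background. Low log2 values are near the dim end of the scale, where differences are compressed. The median probe set had a mean of 4.38 and 10% of the means lay under 2.39.

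Probe sets were named from the platform annotation of 2016. It gave 1 gene symbol for 24956 probe sets, several for 361 and none for 27449. For 24616 of the 24956, the gene identifier was found in a current RefSeq gene table of the rhesus macaque, with the same symbol in each case. Probe sets with several symbols or none were used only in the fit over all probe sets. A probe set without a symbol is unnamed here, which does not mean that it has no gene. Each of the 14132 gene symbols was represented by its probe set with the highest mean over the 6 arrays. There were 6375 genes with more than 1 probe set, and 1139 symbols were uncharacterised LOC names, 4 of them among the changed genes.

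The groups came from the sample titles. Infected and uninfected animals were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), on the deposited values without further normalization or a filter on dim probe sets. The p-values were adjusted with the Benjamini-Hochberg method over all genes or all probe sets, with a threshold of 0.05. Errors of a gene's difference are limma's moderated standard errors, errors of a mean over a list of genes are named where given, and SDs are over the 3 animals of a group. The p-values of single genes and probe sets reflect the spread among 3 animals per group. All tests were two-sided. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, over 30 lists of at least 5 measured genes, adjusted over the lists. With that preset, the p of a list depends on its number of genes. It does not use how the genes vary together among the animals. The lists, with 788 members of which 572 were measured, were fixed from general knowledge of gut tissue and lentivirus infection before the data were examined, as were the design, the other settings to try and the rule for named genes. Camera with an estimated correlation and fry were run as alternatives. Counts adjusted over the list alone use the members' p-values from the same fit.

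Genes were named in the report by a fixed rule. It took the 8 higher and 8 lower genes with the largest log2 difference among those past the threshold without overlap between groups, leaving out LOC symbols. It added the 4 members with the smallest p in the direction of each list past its test, and the 1 member with the smallest p of every other list. CD4, CD8A, MX1, CXCL10, IL17A, MUC2, SI, DEFA5 and LGR5 were named wherever measured, and DEFA5 was not measured by a probe set with that 1 symbol. FABP6 entered through the regional list. PLSCR1, MYH11, REG3G, MLN, CD8B, MUC13, KLF4, ST6GALNAC1, PPARGC1A and ACSL1 fall outside the rule and were chosen after their values were seen.

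The fit was tested on simulated data with the real genes' means and limma's moderated variances, drawn independently for each gene. Of 100 genes changed by 1 log2 unit 85% were called, of 100 changed by 2 log2 units 98%, and 11 unchanged genes were called among 14132 tested. Of 5 lists shifted by 0.5 log2 units all were called, and 0 of 23 lists without a shifted member. Since the simulated genes were independent, this does not show how often lists of correlated genes are called without a shift. In the real data, another split of the animals into groups of 3 called as many as 11 lists. The other settings were quantile normalization, median centring, a filter keeping the brighter probe sets, other variance models, array weights, a block for the replicate number, leaving out each array, a floor at 16 on the linear scale, ordinary t statistics, a threshold of 0.10, a minimum fold of 1.2 (treat), other choices of probe set per gene, and other list tests. Figures were drawn with matplotlib 3.10.9.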

Results

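Gene expression was measured in the jejunum, the middle part of the small intestine, of rhesus macaques. There were 3 animals with chronic infection by simian immunodeficiency virus (SIV), a lentivirus related to HIV, labelled as untreated, and 3 healthy uninfected animals. The labels name the sample as mucosa, give an age of 4 to 6 years for every animal, and call the samples of a group biological replicates. Each animal gave 1 Affymetrix array with 52766 probe sets. Array medians lay between 4.34 and 4.40 on the log2 scale. Pearson correlations across probe sets ran from 0.973 to 0.986 within a group and from 0.970 to 0.977 between groups, so no array duplicated another. The first principal component over 14132 genes, with 40.1% of the variance, separated the groups. The second, with 23.0%, set infected replicate 3 (score -31.7) apart from the other arrays, whose scores lay between -9.80 and 22.30. The number of arrays limits the precision, with a median standard error of 0.17 for the log2 difference of a gene.

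The comparison asks which genes differ in jejunal tissue between chronic SIV infection and health. The infected tissue had far more transcript of ADA, the purine enzyme adenosine deaminase. By the brightest of its 3 probe sets, SLC46A1, the proton-coupled folate transporter, was also far higher. The interferon-induced antiviral genes IFI27, MX1, IFI44 and OAS3 were higher too. Infected tissue had less of PTX3 (a secreted pattern recognition protein), S100A9 (a calcium-binding protein of neutrophils and monocytes), GCG (the precursor of the glucagon-like peptides), ITLN1 (intelectin-1, a carbohydrate-binding lectin of the gut) and MUC2, the main gel-forming mucin of intestinal mucus. Of these genes, only ADA kept its call under all 9 alternatives tried for single genes. For ADA, SLC46A1 and GCG, infection cannot be told apart from the position along the gut where samples were taken. In the moderated limma fit, 78 of 14132 genes passed an adjusted p of 0.05, with 23 higher and 55 lower in infected animals. Their absolute log2 differences ran from 0.84 to 5.29. At an unadjusted p of 0.05 there were 2005 genes. The values of the 2 groups did not overlap for all 78 genes and for 19.9% of all genes tested, against 10% by chance. Over all probe sets, named or not, 64 passed, 20 higher and 44 lower. The gene count was 25 without infected replicate 1, 25 without infected replicate 2, 36 without uninfected replicate 1 and 9 without uninfected replicate 3. For the probe sets it was 13, 19, 10 and 7 in the same order, and 23 without uninfected replicate 2. An exact permutation test of 1 gene with 3 animals against 3 cannot give a p below 0.1, so the p-values given here rest on limma's pooling of variance across genes.

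**Figure D1:**
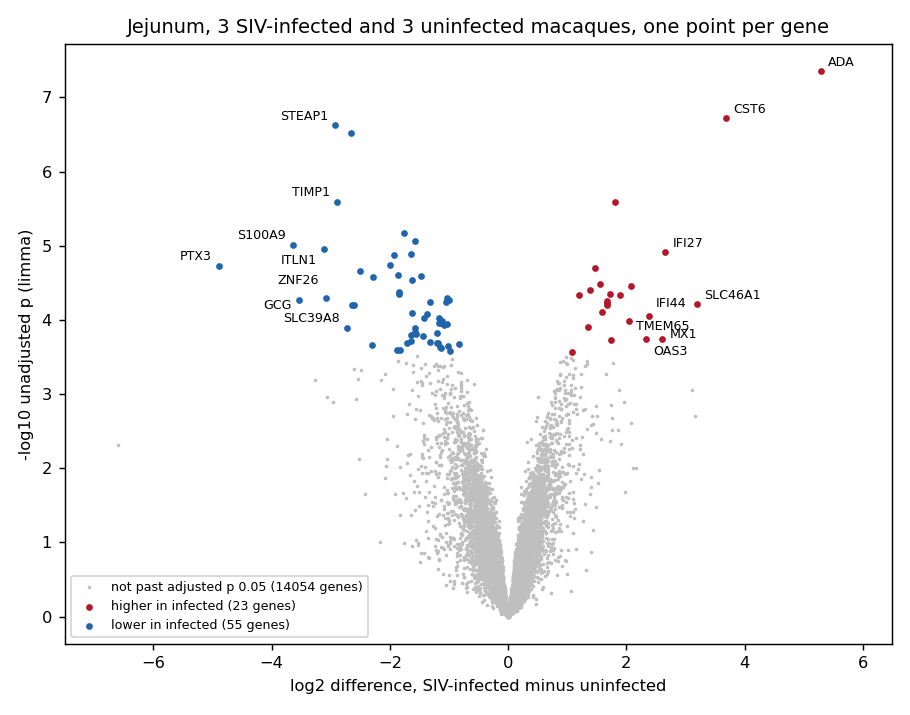
Log2 difference of each of 14132 genes between SIV-infected and uninfected jejunum (horizontal) against -log10 of the unadjusted limma p (vertical), with 23 genes past adjusted p 0.05 and higher in infected animals in red and 55 lower in blue. The 8 named genes of each direction run out to ADA at 5.29 and PTX3 at -4.90.

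ADA had the largest difference of the genes past the threshold. Its log2 value was 11.42 ± 0.39 (SD, n = 3) in infected and 6.14 ± 0.36 (SD, n = 3) in uninfected tissue, a difference of 5.29 ± 0.25 (SE), or 39.0-fold (limma adjusted p = 0.00063). A second ADA probe set differed by 4.79, while another that was dim, with a mean of 4.15, differed by -0.22. CST6, which encodes the protease inhibitor cystatin E/M, was 12.8-fold higher (log2 difference 3.68 ± 0.22 SE, adjusted p = 0.0011). SLC46A1 was 9.13-fold higher (3.19 ± 0.41 SE, adjusted p = 0.022), with 0.63 and 0.19 from its other probe sets. With the mean of its probe sets the SLC46A1 difference was 1.34 and the call was lost. TMEM65, which encodes a mitochondrial inner membrane protein, was 4.14-fold higher (2.05 ± 0.28 SE, adjusted p = 0.030), a call also lost with the mean of its probe sets.

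Among the genes that fell, PTX3 dropped from 7.25 ± 1.24 (SD, n = 3) to 2.35 ± 0.10 (SD, n = 3), a 29.8-fold difference (adjusted p = 0.018). S100A9 was 12.5-fold lower in infected tissue (log2 difference -3.64 ± 0.36 SE, adjusted p = 0.014), GCG 11.7-fold lower (-3.54 ± 0.45 SE, adjusted p = 0.022) and ITLN1 8.63-fold lower (-3.11 ± 0.31 SE, adjusted p = 0.014). STEAP1, which encodes a membrane protein, was 7.58-fold lower (-2.92 ± 0.18 SE, adjusted p = 0.0011). SLC39A8, a zinc and manganese importer, was 6.64-fold lower (-2.73 ± 0.39 SE, adjusted p = 0.032), and its other probe sets differed by between -1.79 and -0.13. For TIMP1, an inhibitor of matrix metalloproteinases, the probe set that stood for the gene was 7.40-fold lower (-2.89 ± 0.24 SE, adjusted p = 0.0060), but its other probe sets differed by -0.07 and 0.04. The zinc finger gene ZNF26 had the same split, with -3.08 from the brightest probe set (adjusted p = 0.022) and -0.09 and -0.04 from the others. With the mean of all its probe sets, the difference was 3.29 for ADA, 1.08 for HSPH1, -1.30 for SLC39A8, -0.97 for TIMP1 and -1.07 for ZNF26, each still past the threshold. For TIMP1 and ZNF26 that mean is carried by the 1 probe set that differed, so it adds no separate support for their calls. ADA, CST6 and STEAP1 passed the threshold when each array was left out in turn. Among the 22 named genes past the threshold, the other 19 lost it under 1 or more of 9 alternatives, with an adjusted p of at most 0.172. IFI27, ITLN1 and TIMP1 lost it only without uninfected replicate 3 (adjusted p = 0.082, 0.082 and 0.056) and S100A9 only without infected replicate 1 (0.057), while each of the remaining 15 lost it with 3 to 6 of the arrays left out. The lower means of PTX3 (2.35), GCG (2.94), S100A9 (3.54), STEAP1 (3.68) and CST6 (4.05) lay below the median probe set mean of 4.38, so that the sizes of their folds are uncertain.

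**Figure D2:**
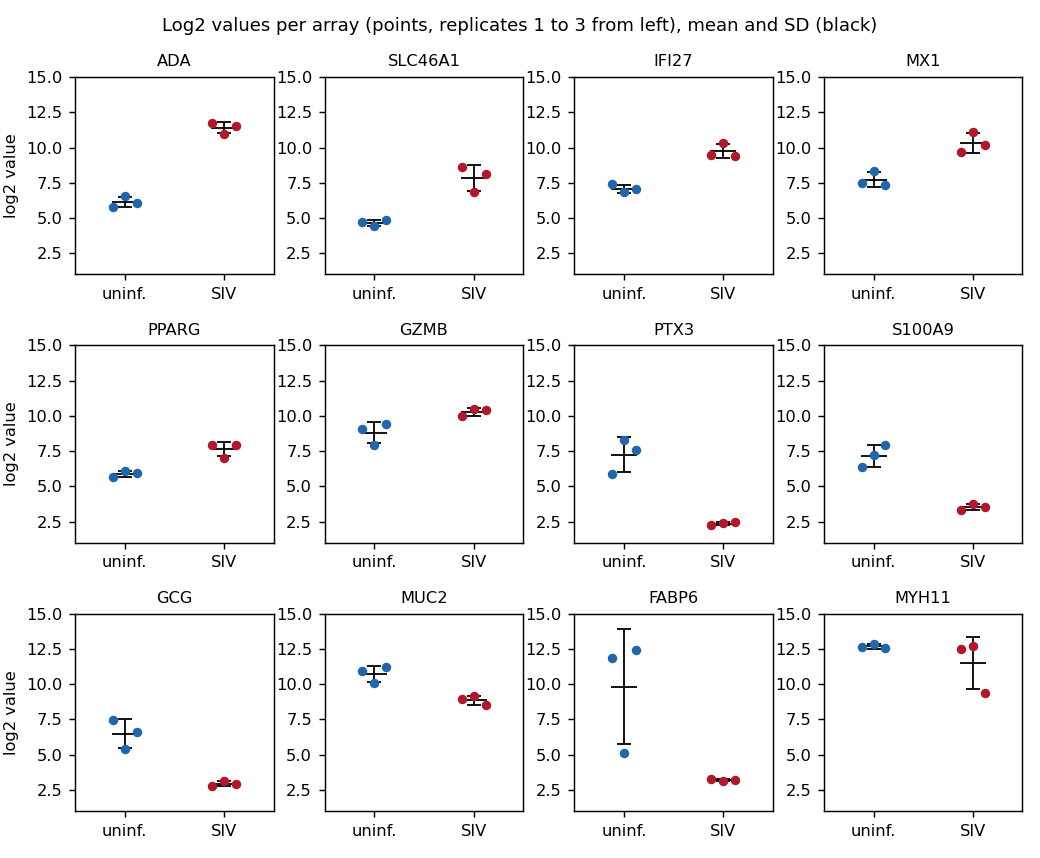
Log2 values of 12 genes on each array (points, replicates 1 to 3 from left to right) for 3 uninfected (blue) and 3 SIV-infected (red) animals, with the mean (wide bar) and SD (whiskers) of each group in black. ADA lies at 11.42 in infected and 6.14 in uninfected animals without overlap, whereas FABP6 is at 5.12 in uninfected replicate 2 against 11.88 and 12.42 in the other uninfected animals, and MYH11 is at 9.36 in infected replicate 3.

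Interferon-stimulated genes were higher as a group in infected tissue. Of 39 measured, 4 rose past the threshold over all genes (IFI27, MX1, IFI44 and OAS3) and 35 did not pass it. Adjusted over the list alone, 25 were higher and 1, PLSCR1 (-0.68), was lower. IFI27 was 6.32-fold higher (log2 difference 2.66 ± 0.27 SE, adjusted p = 0.014), MX1, a dynamin-like antiviral GTPase, 6.09-fold (2.61 ± 0.39 SE, adjusted p = 0.041), IFI44 5.20-fold (2.38 ± 0.32 SE, adjusted p = 0.028) and OAS3, a sensor of double-stranded RNA, 5.01-fold (2.32 ± 0.35 SE, adjusted p = 0.041). The other OAS3 probe sets differed by 1.94 and 0.35, and with the mean of its probe sets the OAS3 difference was 1.54 and the call was lost, as was that of IFI44. The median log2 difference of the list was 0.81, and its camera test, which compares a list with all other genes, gave an adjusted p = 7.2e-16 with the preset correlation. It was lost at an adjusted p = 0.305 with an estimated correlation. The list of interferon-gamma response and antigen presentation genes did not pass (27 measured, camera adjusted p = 0.716). Its member with the smallest p, the proteasome activator gene PSME2, differed by 0.89 (adjusted p = 0.110), and the chemokine gene CXCL10 by 1.44 (adjusted p = 0.396).

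Cytotoxic lymphocyte genes were also higher as a set (22 measured, median 0.39, camera adjusted p = 7.7e-06, and adjusted p = 0.461 with an estimated correlation). None of the 22 passed over all genes, and 5 were higher adjusted over the list alone, CD8B (0.81) among them. The members with the smallest p were NKG7 (log2 difference 1.49), granulysin (GNLY, 1.39), granzyme B (GZMB, 1.48) and CST7 (1.14), with adjusted p from 0.095 to 0.138 over all genes. The other GNLY probe set, with a mean of 5.49, differed by -0.005. CD8A differed by 0.85 ± 0.27 (SE, adjusted p = 0.226), with 0.45 from its other probe set, and CD4 by -0.35 ± 0.24 (SE, adjusted p = 0.550). The pan-T-cell list (14 measured, adjusted p = 0.446), the CD4 T helper and Th17 list (18 measured, adjusted p = 0.446), and the T cell exhaustion and activation list (14 measured, adjusted p = 0.311) did not pass. In these, UBASH3A differed by 0.57 and the checkpoint receptor gene CTLA4 by 0.36. IL17A, with means of 2.74 and 2.92 near the low end of the scale, differed by -0.18 ± 0.11 (SE, adjusted p = 0.510). Plasma cell and immunoglobulin genes were higher as a set (11 measured, 0 past the threshold over all genes, 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.036, and adjusted p = 0.461 with an estimated correlation). FKBP11 (0.70), PRDM1 (0.82), SSR4 (0.42) and SEC11C (0.40) led that list. It did not pass without infected replicate 1 (adjusted p = 0.090), infected replicate 2 (0.111) or uninfected replicate 2 (0.195), and passed under 7 of 17 alternatives in all. B cell genes did not pass (12 measured, adjusted p = 0.359), and FCRL1 differed by 0.55.

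Neutrophil genes were lower as a set (10 measured, median -0.25, camera adjusted p = 0.0013, and adjusted p = 0.294 with an estimated correlation). S100A9 passed over all genes, and 3 members were lower adjusted over the list alone. Those were S100A9, its partner S100A8 (-3.26 ± 0.60 SE, adjusted p = 0.072) and the gelatinase gene MMP9 (-1.46 ± 0.27 SE, adjusted p = 0.073), whereas CSF3R differed by -0.44. The list's mean was -0.93. The lists for macrophages and dendritic cells (24 measured, adjusted p = 0.446), mast cells (8 measured, 0.885), and inflammatory cytokines and the inflammasome (20 measured, 0.270) did not pass over all arrays. The inflammatory list passed, lower, without uninfected replicate 1 (adjusted p = 0.027). In them, CLEC7A differed by -0.45, SLC18A2 by -0.40 and the monocyte chemokine gene CCL2 by -2.54 ± 0.46 (SE, adjusted p = 0.072). The red blood cell list did not pass (7 measured, adjusted p = 0.311), though GYPC, which encodes glycophorin C, fell by 1.32 on the log2 scale (adjusted p = 0.042).

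Goblet cell and mucus genes were lower as a set (20 measured, median -0.37, camera adjusted p = 0.0028, and adjusted p = 0.461 with an estimated correlation). Over all genes, MUC2 was 3.68-fold lower (log2 difference -1.88 ± 0.30 SE, adjusted p = 0.048), SYTL2 was 2.22-fold lower (-1.15 ± 0.18 SE, adjusted p = 0.045), and 18 members did not pass. Adjusted over the list alone, 9 were lower and 3 were higher (MUC13, KLF4 and ST6GALNAC1, by 0.56, 0.81 and 0.57). The trefoil factor gene TFF3 differed by -1.46 (adjusted p = 0.075) and FCGBP, a component of mucus, by -1.95 (adjusted p = 0.077). The MUC2 call was lost with each array but uninfected replicate 2 left out, and the SYTL2 call with any array left out, at adjusted p of up to 0.168 and 0.143. Beside these genes, FABP6, the bile acid-binding protein of the ileum, had log2 values of 3.26, 3.14 and 3.23 in infected animals 1 to 3 and of 11.88, 5.12 and 12.42 in uninfected animals 1 to 3. That difference of -6.60 ± 1.69 (SE) did not pass (adjusted p = 0.148), and was -8.94 (adjusted p = 4.8e-05) without uninfected replicate 2.

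Other epithelial lists did not pass over all arrays. The Paneth cell and antimicrobial list (22 measured, adjusted p = 0.146) held ITLN1 and REG3G, an antibacterial lectin gene, lower past the threshold, and passed without uninfected replicate 2 (adjusted p = 0.047). The enteroendocrine list (14 measured, adjusted p = 0.659) held GCG lower and MLN, the gene of the hormone motilin, higher past the threshold (log2 differences -3.54 and 1.59). The regional list of gastric, duodenal and ileal genes (11 measured, adjusted p = 0.270), which holds FABP6, passed without uninfected replicate 2 (adjusted p = 0.047). The absorptive enterocyte list (37 measured, adjusted p = 0.559) held SLC46A1 higher, and sucrase-isomaltase (SI) differed by 0.01 ± 0.12 (SE, adjusted p = 0.970). The list of xenobiotic and bile acid handling genes (23 measured, adjusted p = 0.559) held NR0B2, a nuclear receptor induced by bile acids, which was 3.70-fold higher (log2 difference 1.89 ± 0.23 SE, adjusted p = 0.022). The tuft cell list (8 measured, adjusted p = 0.311), the epithelial junction list (28 measured, 0.612) and the intestinal stem cell list (15 measured, 0.944) had no member past the threshold. In them, BMX differed by -0.76, CLDN15 by 0.56, CD44 by -0.51 and the stem cell receptor gene LGR5 by -0.03 ± 0.13 (SE). For the enteroendocrine list, the camera direction was higher while the median (-0.02) and mean (-0.10) were below 0. The absorptive enterocyte mean (-0.04), the stem cell mean and the mast cell median (0.01) likewise had the opposite sign to the camera direction.

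Genes of lipid handling and of mitochondrial respiration were higher as sets in infected tissue, a call that both lists lost when the most variable probe set stood for each gene (adjusted p = 0.051 and 0.235). Of 25 measured genes of lipid absorption and fatty acid oxidation, PPARG, a lipid-sensing nuclear receptor, rose 3.32-fold (log2 difference 1.73 ± 0.26 SE, adjusted p = 0.041) and 24 did not pass over all genes. Adjusted over the list alone, 4 were higher and 2, PPARGC1A (-0.68) and ACSL1 (-2.09), were lower (median 0.35, camera adjusted p = 0.0011, and adjusted p = 0.294 with an estimated correlation). SLC27A4, a fatty acid transport gene, differed by 1.74 (adjusted p = 0.094), CREB3L3 by 0.82 and ACSL5 by 0.67. The 27 measured genes of mitochondrial oxidative phosphorylation had small differences, 23 above 0 and 4 below, with a median of 0.22 (camera adjusted p = 0.0011, and adjusted p = 0.611 with an estimated correlation). None passed singly over all genes or adjusted over the list alone, and NDUFS1 (0.59), UQCRQ (0.35), NDUFS3 (0.36) and NDUFA2 (0.35) had the smallest p. Cell cycle genes were higher as a set (30 measured, 0 past the threshold singly or adjusted over the list alone, median 0.23, camera adjusted p = 0.0033, and adjusted p = 0.618 with an estimated correlation). FOXM1 (0.63), CDCA3 (0.50), the proliferation marker gene MKI67 (0.82) and NCAPG (0.66) led it. The cell cycle call was lost without infected replicate 3 (adjusted p = 0.308) or uninfected replicate 2 (0.104). Stress lists did not pass. In the immediate early and heat shock list (15 measured, adjusted p = 0.143) the chaperone gene HSPH1 was 3.20-fold higher (1.68 ± 0.21 SE, adjusted p = 0.022), and in the unfolded protein response list (14 measured, adjusted p = 0.146) MANF differed by 0.88 (adjusted p = 0.059).

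Genes of the tissue's stroma were lower as sets. Of 27 measured extracellular matrix and fibroblast genes, TIMP1 fell past the threshold over all genes, through 1 of its 3 probe sets. Adjusted over the list alone, 7 were lower (median -0.45, camera adjusted p = 7.7e-06, and adjusted p = 0.450 with an estimated correlation). Decorin (DCN) differed by -0.80 (adjusted p = 0.066), COL14A1 by -1.38 (adjusted p = 0.068) and fibronectin (FN1) by -0.99 (adjusted p = 0.081). All 13 measured smooth muscle genes had differences below 0 (median -1.18, camera adjusted p = 0.0011, and adjusted p = 0.611 with an estimated correlation), but none passed singly over all genes or adjusted over the list alone. ACTN1 (-0.96), CALD1 (-1.58), KCNMB1 (-1.23) and TPM1 (-0.72) had the smallest p. The median log2 value of the smooth muscle list was 10.27, 10.79 and 6.56 in infected animals 1 to 3 and 10.20, 10.76 and 10.08 in uninfected animals 1 to 3. Without infected replicate 3 the smooth muscle call was lost (adjusted p = 0.216, median -0.25), while the matrix list still passed (adjusted p = 0.0053, median -0.32). Endothelial genes were lower as a set (17 measured, 0 past the threshold singly or adjusted over the list alone, median -0.19, camera adjusted p = 0.012, and adjusted p = 0.611 with an estimated correlation). LYVE1 (-0.57), CDH5 (-0.63), SELE (-0.42) and EMCN (-0.48) led that list, which did not pass without infected replicate 3 (adjusted p = 0.205) or uninfected replicate 2 (0.103), and passed under 11 of 17 alternatives in all.

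In all, 11 of the 30 lists passed the camera test with its preset correlation, 6 higher and 5 lower. None of the 30 passed with an estimated correlation, where the smallest adjusted p was 0.294 and 3 lists (interferon-stimulated, neutrophil and lipid) had an unadjusted p under 0.05. In limma's fry test, which asks whether the genes of a list move on balance in 1 direction, 4 lists passed, namely these 3 and the unfolded protein response list.

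**Figure D3:**
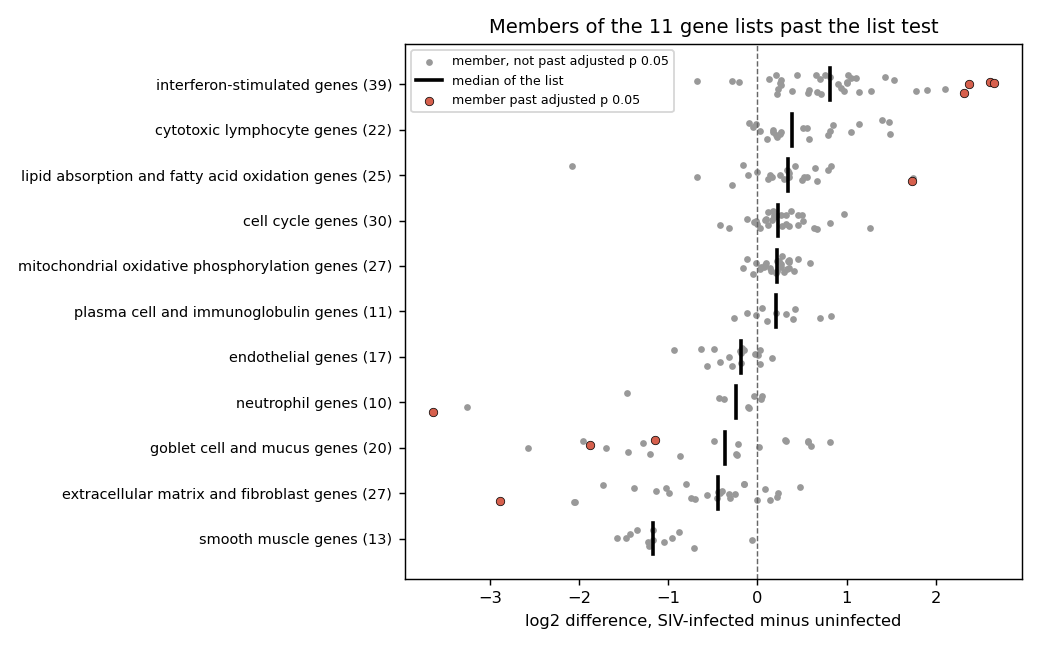
Log2 differences between SIV-infected and uninfected jejunum (horizontal) of each measured member of the 11 gene lists past the camera test, with the number measured in brackets, members past adjusted p 0.05 over all genes in red and the median of each list as a black bar. The medians run from -1.18 for smooth muscle genes to 0.81 for interferon-stimulated genes.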

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

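The array carries 9 probe sets whose identifiers begin with AY588945. They have no gene symbol here, the tables used here do not say what they detect, and they enter the report only through the count over all probe sets. In 5 of them an infected array exceeded the highest uninfected array by more than 1 log2 unit, and each time that array was infected replicate 2. The excess was 5.58 for CDS9, where infected replicate 2 read 7.98 and the uninfected arrays between 1.83 and 2.40. It was 4.37 for CDS8, 3.49 for CDS7, 1.42 for CDS6 (its first probe set) and 1.18 for CDS2. Infected replicates 1 and 3 read 2.14 and 2.87 for CDS9. Of 674 probe sets with identifiers beginning with NC, 3 exceeded the uninfected arrays by over 1 log2 unit. No probe set of either class had an uninfected array above all infected arrays by that much. Over the whole array, 1.68% of probe sets had an infected array above all uninfected ones by over 1 log2 unit, and 1.60% the reverse. No explanation was tested, and the excesses of over 1 log2 unit in the AY588945 class come from 1 animal.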

How the results depend on the processing

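The main counts were 78 genes, 64 probe sets and 11 lists. Leaving out 1 array at a time gave 9 to 58 genes, 7 to 43 probe sets and 8 to 12 lists, with fewer samples in each fit. Quantile normalization and median centring kept 71 and 71 of the 78 genes. Keeping the brighter probe sets raised the probe set count to 113, with fewer tested. Ordinary t statistics called 0 genes and 0 probe sets, with 1528 genes and 4275 probe sets at an unadjusted p under 0.05. A threshold of 0.10 gave 237 genes and 210 probe sets, and limma's treat against a fold of 1.2 gave 38 and 41. The most variable probe set per gene gave 7 lists, without the plasma cell, lipid, oxidative phosphorylation and endothelial lists, an estimated correlation 0 and fry 4, of which 3 were among the 11; the cause of the first was not tested. With the replicate number as a block, 67 genes, 47 probe sets and 10 lists passed, and 48, 30 and 10 of them were among the main calls. The correlations of deviations between infected and uninfected animals with the same number were -0.17, 0.07 and 0.10. Those with different numbers ran from -0.20 to 0.17. This gave no sign that the numbers pair the animals, but 3 animals per group are too few to exclude it. The robust variance model was not run for lists, since camera has no such setting. Over named genes, 582 values under alternatives stayed on their side of the threshold, 89 lost the threshold and 4 gained it. Over single lists these were 468, 36 and 5. No gene or list that passed in the main or the alternative fit reversed. Direction was not compared where neither fit passed. No value could be set against background, since detection calls were not used.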

Other observations

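The tests of ADA probe sets, of the clock genes, of glucocorticoid-induced genes and with S100G or ZFP36 left out were chosen only after the results were seen, as were the genes named here beyond those of the report. Leaving out each array was set beforehand, but its use to weigh the muscle content of infected replicate 3 was chosen afterwards. DNAJA1, a co-chaperone gene, rose 2.78-fold in infected tissue (log2 difference 1.48 ± 0.16 SE, limma adjusted p = 0.018). STIP1 (0.98, adjusted p = 0.056), AHSA1 (0.99, 0.059) and FKBP4 (1.30, 0.059) did not pass, and neither did the heat shock list of the report, although its member HSPH1 did. In the opposite direction, CEBPD, a transcription factor of the acute phase response, was lower (-1.44 ± 0.21 SE, adjusted p = 0.039), as was BCL6 (-1.62 ± 0.22 SE, adjusted p = 0.026), and SOD2 differed by -1.54 (adjusted p = 0.055). All of these had 3 infected animals on 1 side of 3 uninfected animals.

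For the 3 main counts, there are 10 splits of the 6 animals into groups of 3, too few for a share under 0.05. The real split gave 78 genes and the highest other split 1, and 64 probe sets against 0, so that 1 of 10 splits reached each real count. For the lists, 2 of 10 splits reached the real 11, since another split also gave 11. In that split, infected replicate 1 stood with uninfected replicates 1 and 2.

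ADA and SLC46A1, abundant in the upper small intestine, were higher in infected animals, while FABP6 and GCG, more abundant toward the ileum, were lower there or, for FABP6, at the dim end in all 3 infected animals. A candidate explanation is that the uninfected samples were taken farther along the small intestine. That explanation was tested in 16 proximal and 13 distal marker genes, of which 7 and 3 belong to lists already tested. They were chosen as genes whose own values had not been examined, but S100G was also among genes picked out after their values were seen. The mean log2 difference of proximal minus distal markers was 0.46 ± 0.28 (SE over the genes), with a two-sided permutation p = 0.126. Of the proximal markers 9 were higher and 7 lower, and of the distal markers 6 were higher and 7 lower. Among the higher distal markers, INSL5, AQP8, SLC5A8 and SLC9A3 read between 2.44 and 4.79 on every array. At such dim values they could show little of a difference in position, which weakens the test. The other higher ones, LYPD8 (0.36) and SLC22A5 (0.58), were brighter, and HOXB8 (-0.30), a lower one, was also dim. S100G (3.10) carried much of the difference, which was 0.27 without it, and NPC1L1 (-0.91), ABCG8 (-0.68) and ABCG5 (-0.60) went against the explanation. Among genes examined earlier, SLC10A2 (-1.64) and SLC40A1 (1.71) went with it, and CYBRD1 (-0.91) and PYY (-0.01) did not. None of these 4 passed the threshold. MLN, also a gene of the upper small intestine, was higher in infected animals past the threshold, which goes with the explanation. The test of marker genes did not decide, so position along the gut and infection cannot be told apart for these genes. Position was not tested for the goblet genes or ITLN1. Among uninfected animals, SYTL2, MUC2, TFF3, FCGBP and ITLN1 were lowest in replicate 2, as FABP6 was. A sequence variant under 1 probe set as the source of the ADA difference is argued against by the other ADA probe set above log2 5, which differed by 4.79 ± 0.36 (SE). That value was known when this test was chosen. The third ADA probe set, with a mean of 4.15, fell under that cut and differed by -0.22.

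The lower smooth muscle list rests on infected replicate 3. MYH11 read 9.36 there and between 12.49 and 12.87 on the other arrays, on a scale that ends at 14.21. The labels name the sample as mucosa, and the other samples may hold more muscle than that name implies. Less muscle layer in infected replicate 3 may account for the list's call, since the camera adjusted p was 0.216 without that sample. The extracellular matrix list still passed without infected replicate 3 (camera adjusted p = 0.0053 with the preset correlation), so its call did not need that sample. Its median was -0.32 without it and -0.45 with all arrays. Camera with an estimated correlation did not call this list over all arrays (adjusted p = 0.450), so the same explanation is not excluded. Whether infection lowers matrix genes or the samples differ in depth of tissue in another way was not tested.

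ARNTL, a core gene of the circadian clock, fell by 1.63 on the log2 scale in infected tissue (adjusted p = 0.019). CIART (1.24), TEF (0.58) and NFIL3 (-0.84) had been picked out with it and did not pass. Different times of day at sampling may account for this, but the remaining clock genes could not decide it. They were PER3 (0.75), BHLHE41 (0.44), NR1D1 (0.43), PER2 (0.17) and PER1 (0.00) of the opposite phase against CLOCK (-0.30), with a mean difference of 0.66 ± 0.21 (SE carried over from the genes' own limma errors). The two-sided exact permutation p of 0.167 is the smallest that 5 genes against 1 can give. A clock shifted by infection was not tested. A difference in glucocorticoid exposure also stays open. Of 9 glucocorticoid-induced genes 3 were higher and 6 lower (mean -0.51 ± 0.21, SE over the genes), with a camera p = 0.037 for the list with the preset correlation and 0.140 with an estimated correlation. With the preset correlation, the p was 0.137 without infected replicate 2, 0.073 without uninfected replicate 2 and 0.059 without ZFP36, whose value of 4.03 in infected replicate 3 lay below those of 7.79 to 8.65 on the other arrays. Sampling times were not used here, and genes are not independent replicates.

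Uninfected replicate 2 had lower values than the other arrays for 4 of 5 bright mitochondrial probe sets. It read 8.60 for MmuMitochon.10 against 13.64 to 13.77 elsewhere, 11.04 for MmuMitochon.3 against 13.0045 to 13.2635, 12.88 for MmuMitochon.4 against 13.87 to 14.11 and 12.40 for MmuMitochon.6 against 13.44 to 13.57. For MmuMitochon.12 it was the highest array, at 13.21.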
